A study of Ceratotherium simum simum with 6 samples.

How the data were processed

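RNA-seq libraries of granulosa cells from 2 southern white rhinoceroses (Ceratotherium simum simum) were analysed, 3 libraries per animal. Per the labels' protocols, total RNA was isolated with the PicoPure kit and libraries were made with the NEBNext Ultra II RNA kit for Illumina sequencing. The labels do not say whether the directional form of that kit was used. Trimmomatic, HISAT2 and StringTie are listed in the submitters' processing notes, without versions or settings. The genome build and the strand setting of the counting are not given in the sources used here. Per the file headers and values, the deposited values are whole-number read counts, not normalized, in 5 files per assembled transcript and in 1 file, that of rhino 2 replicate 1, per assembled gene. A deposited table of transcript positions gives the scaffold, start, end, strand and, for annotated transcripts, a gene name for each of 55787 transcripts, and scaffold coordinates below are those of that table. No column of another sample was present.

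Transcript counts were summed to the 40656 assembled genes, so that all 6 libraries were on the same features. Of these genes, 22569 carried a gene name and 18087 carried only an assembly identifier. Because the libraries placed their counts on different strands (values in the report), an unnamed gene whose exons covered at least 50% of the shorter of the 2 exonic lengths on the opposite strand of a named gene was joined to that named gene, with bedtools 2.31.1. This joined 14075 unnamed genes and left 25906 loci. The joining was chosen after the counts were examined, and the tests were also run on the genes as deposited. Only 10525 named loci had an opposite-strand model, and 12044 had none. A count of 0 at a locus of the latter kind says nothing about its RNA in the 5 libraries whose counts lay on the opposite strand.

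CPM values (read counts scaled to a common library total of 1e+06) were computed here from the deposited counts with the library total as the denominator. The totals were between 672410 and 13288936. The smallest non-zero value, 1 count, is worth 0.0753 CPM in rhino 1 replicate 1 and 1.49 CPM in rhino 1 replicate 2. Where a locus had no counts, the upper limit was taken as 3 counts of the library total. For the share of counts in a single library, 95% Wilson binomial intervals were computed. Reads carry no molecular identifiers here, so intervals and limits cover counting error only.

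The animals were compared with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, glmQLFit and glmQLFTest, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p for a gene below is from edgeR's quasi-likelihood test unless another tool is named. Statements that a gene passed or did not pass the threshold rest on that test of all libraries unless another fit or tool is named. Fold changes are rhino 2 over rhino 1, on the log2 scale. Only 1 animal stands in each group, and nothing in the labels says whether the libraries of an animal came from separate follicles, collections or aliquots, so p-values measure the spread between these libraries, which may be technical. Gene lists were tested with camera (preset correlation of 0.01, and again with an estimated correlation) and with fry, both in limma 3.58.1, on log2 CPM with a prior count of 2. The 30 lists, 23 of processes and 7 of cell type markers, held 778 symbols. Of these, 352 matched a name in the files as written, 356 matched through the UniProt entry name that the files use in place of a symbol (CP19A for CYP19A1, MIS for AMH), and 70 did not match. Lists with fewer than 2 tested members were not tested as lists.

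The groups, tests, gene lists and the rule for the genes named were set before the data were examined. By that rule, the text names the 12 largest positive and 12 largest negative log2 fold changes among genes with a symbol that passed the threshold, did not overlap between the animals and reached a mean of 10 CPM in the higher animal. It also names the 20 most abundant genes with a symbol, a panel of 25 granulosa genes, up to 4 members per list by size of fold change, and up to 3 members per marker list by level. Some members that the rule selects are not reported here. A locus was called detected in an animal at 1 CPM or more in each of its 3 libraries. Loci were ranked for abundance by the mean of the 2 animals' mean CPM. Correlations between libraries are across loci of log2(CPM + 1), and loci are not independent replicates.

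Alternatives were DESeq2 size factors, no filter on low counts, a mean of at least 5 CPM in either animal, DESeq2 1.42.0, limma-voom, a minimum absolute log2 fold change of 1, the replicate number as a block, each library left out in turn and the removal of mitochondrial DNA genes. Detection was repeated at 0.1 and 5 CPM and in fewer libraries. Added after the data were seen were the genes as deposited, strands joined at any overlap, and only loci modelled on both strands. The tests were checked on simulated counts for 8532 loci with the totals of these 6 libraries and 200 changed loci. Of 50 loci changed by each size, 4% were recovered at 2-fold, 24% at 4-fold, 64% at 8-fold and 62% at 16-fold, and 3 of 80 calls were false. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.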

Results

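The transcriptome of granulosa cells, the somatic cells that surround the oocyte in the ovarian follicle and make oestradiol and inhibin, was measured by RNA-seq in 2 wild-type southern white rhinoceroses. The labels describe the cells as in vivo and taken before IVM, in vitro maturation of the oocyte. Each animal, rhino 1 and rhino 2, had 3 libraries. The totals of rhino 1 were 13288936, 672410 and 1449450 counts for replicates 1, 2 and 3, and those of rhino 2 were 1523904, 703708 and 1078480. The deepest library held 19.8 times the counts of the smallest.

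The libraries differed in the strand that held their counts. In rhino 1 replicate 1, named genes took 94.5% of the counts (95% Wilson interval 94.4 to 94.5), and unnamed genes on the opposite strand of a named gene took 0.696% (0.692 to 0.701). In rhino 1 replicate 2 these shares were 2.31% (2.28 to 2.35) and 86.9% (86.8 to 86.9), and in rhino 1 replicate 3 they were 2.33% (2.30 to 2.35) and 90.2% (90.2 to 90.3). In rhino 2, replicate 1 had 2.61% (2.59 to 2.64) and 88.8% (88.7 to 88.8), replicate 2 had 2.46% (2.42 to 2.49) and 86.1% (86.0 to 86.2), and replicate 3 had 2.53% (2.5 to 2.56) and 87.5% (87.4 to 87.5). Among named loci with at least 50 counts, the median share on the opposite strand was 0% in rhino 1 replicate 1 and 100% in each of the other 5 libraries. Of the 100129 introns in the joined opposite-strand models, 93679 (93.6%) were identical to an intron of the named gene. Values below, except those on the genes as deposited, are sums over both strands of a locus where both were modelled. The 12044 named loci with no opposite-strand model have counts of 1 strand only.

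**Figure D1:**
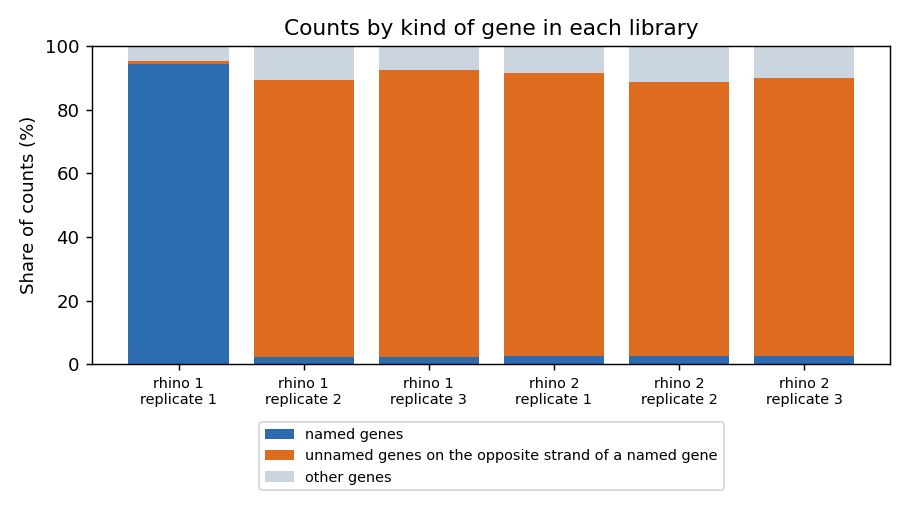
Share of counts (percent, vertical axis) in named genes, in unnamed genes on the opposite strand of a named gene and in other genes, stacked for each of the 6 libraries. Named genes hold 94.5% of counts in rhino 1 replicate 1 and between 2.31% and 2.61% in the other 5 libraries.

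The 20 most abundant genes with a symbol held genes of secreted and matrix proteins and of the granulosa hormone inhibin beside genes of the cytoskeleton, of translation and of protein folding. GDN, the gene SERPINE2 that encodes the protease inhibitor protease nexin-1, came first among genes with a symbol, at 17159 ± 3680 CPM in rhino 1 and 19879 ± 4103 CPM in rhino 2 (mean ± SD, n = 3 in each here and below; scaffold 37, 14799583 to 14859344). The translation factor gene EF1A1 followed at 11918 ± 190 and 22610 ± 708 CPM, and PGBM, the gene HSPG2 of the basement membrane proteoglycan perlecan, at 15604 ± 6392 and 12060 ± 2103 CPM. INHA, which encodes the alpha subunit of inhibin, stood at 11167 ± 2457 and 6860 ± 1620 CPM (scaffold 37, 18617791 to 18620668). Further down came the thrombospondin genes TSP1 (3924 ± 1309 and 9034 ± 3539 CPM) and TSP4 (3555 ± 1070 and 3781 ± 972 CPM), the actin genes ACTG and ACTB, vimentin (VIME), the collagen-modifying enzyme gene PLOD2 and the laminin gene LAMA1. CXA1, the gene GJA1 of the gap junction protein connexin 43, had 2817 ± 598 and 2453 ± 368 CPM. The rest of the 20 were TCTP, RSSA, BIP, FRIH, HS90A, INHBB, JBP2 and a copy of NU4LM. JBP2, with no opposite-strand model, had 31.7 CPM in rhino 1 replicate 1 and between 2854 and 4523 CPM in the other libraries, and the NU4LM copy had 328 CPM against 1947 to 4030 CPM. EF1A1, PGBM, RSSA, LAMA1, FRIH and NU4LM are names on more than 1 locus, so their counts are uncertain. The top 10 loci held 10.3% of the mean profile (SD over libraries 1.32), the top 50 held 19.6% (SD 1.77) and the top 100 held 26.5% (SD 2.16).

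Detection covered 6431 loci in rhino 1 and 7556 in rhino 2, with 5758 in both, 673 in rhino 1 only and 1798 in rhino 2 only. Of the loci detected in both, 5530 had a gene name. The counts moved by over 1.5 times with the number of libraries required: 8643 loci reached 1 CPM in at least 2 of 3 libraries of both animals and 10430 in at least 1. The order of the loci detected in 1 animal only turned with these choices. Without rhino 1 replicate 2 it was 2088 in rhino 1 only and 703 in rhino 2 only, and the counts were 1006 and 707 in at least 2 libraries and 3873 and 376 in at least 1. Strand also bears on them, since loci modelled on 1 strand can hardly be detected in all 3 libraries of rhino 1. Among loci modelled on both strands, 6127 were detected in rhino 1 and 6619 in rhino 2. Of those loci, 5500 were detected in both, 627 in rhino 1 only and 1119 in rhino 2 only.

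Of 27 members of the granulosa identity list matched, 22 had counts in every library of both animals. Among the others, named after their values were seen, AMHR2 was at 0 in rhino 1 replicate 2 and rhino 2 replicate 3, ESR2 and TFIP8 had counts in rhino 1 replicate 1 alone. GATM and VMAT2 had none. The FSH receptor gene FSHR had 115 ± 65.5 CPM in rhino 1 and 185 ± 46.7 CPM in rhino 2. FOXL2, a transcription factor that maintains granulosa fate, had 409 ± 220 and 246 ± 69.4 CPM. FST, which encodes the activin-binding protein follistatin, had 2341 ± 674 and 2030 ± 513 CPM. The nuclear receptor genes NR5A2 (1126 ± 247 and 1456 ± 422 CPM) and NR5A1, listed as STF1 (68.3 ± 7.84 and 50.9 ± 2.27 CPM), GATA4 (160 ± 68.8 and 160 ± 16.9 CPM) and HSD17B1, listed as DHB1 (374 ± 177 and 504 ± 205 CPM), did not pass the threshold between the animals, with adjusted p between 0.668 for NR5A2 and 0.994 for GATA4. FSHR (adjusted p = 0.623), FOXL2 (0.736), FST (0.970), GJA1 (0.959) and INHA (0.503) did not pass it either. Other genes of the panel had 0 counts in at least 1 library. STAR, the cholesterol transporter gene that rises in luteinising cells, had 7.37, 0 and 12.4 CPM in rhino 1 and 36.1, 8.53 and 58.4 CPM in rhino 2, and PGR, listed as PRGR, had 0 counts in replicate 2 of each animal and at most 13.9 CPM elsewhere. CYP11A1, the side-chain cleavage enzyme gene, had 71.7 ± 31.6 CPM in rhino 1 and 27.6, 0 and 13 CPM in rhino 2. IGFBP5, listed as IBP5, had 7.60, 40.2 and 8.97 CPM in rhino 1 and was at 0 in replicates 2 and 3 of rhino 2. TNFAIP6 (TSG6) and AREG had no counts in any of the 6 libraries, which by counting error alone allows up to 0.226 CPM in the deepest and 4.46 CPM in the smallest. Higher levels are possible, since 202 loci for which the other libraries predicted at least 20 counts were listed at 0 in rhino 1 replicate 2. In rhino 1 replicate 1, a locus predicted at 220 counts was at 0. HAS2 (HYAS2) had 11.9 CPM in rhino 1 replicate 2 and no counts elsewhere. ESR2 had 2.56 CPM in rhino 1 replicate 1, and its locus has no opposite-strand model.

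Between the animals, genes of cell division were higher in rhino 1, and immediate early genes, which cells switch on within minutes of a stimulus, were higher in rhino 2. These are camera's calls on the 2 lists. Cell cycle genes had adjusted p = 0.031 with an estimated correlation, and the call on immediate early genes was lost, with adjusted p = 0.103 with an estimated correlation. The largest difference that passed the test towards rhino 2 was that of NR4A1, an orphan nuclear receptor gene of the immediate early class (scaffold 17, 17377261 to 17398256, minus strand). It had 55.4 ± 7.30 CPM in rhino 1 and 1381 ± 198 CPM in rhino 2 (log2 fold change 4.73, SE 0.24, adjusted p = 0.0020). The largest towards rhino 1 was that of GSTA1, a glutathione transferase gene expressed in steroid-making cells (scaffold 13, 51894824 to 51903183, minus strand). It had 1469 ± 686 CPM in rhino 1 and 42.8 ± 10.5 CPM in rhino 2 (log2 fold change -5.00, SE 0.45, adjusted p = 0.018), and since the name stands on 3 loci of a multigene family its count is uncertain. AMH, the anti-Mullerian hormone of growing follicles, listed as MIS (scaffold 40, 12665089 to 12667664), rose from 83.7 ± 6.32 to 349 ± 74.4 CPM (log2 fold change 2.16, SE 0.22, adjusted p = 0.019).

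Of 8532 loci tested, 47 passed the threshold, 21 higher in rhino 2 and 26 higher in rhino 1, and 1101 had an unadjusted p under 0.05. All 47 had 3 libraries of one animal above all 3 of the other, as had 24.4% of the tested loci, where chance gives 10%. Of the 47, 44 had a symbol. Those higher in rhino 2 included BTG2, an antiproliferative immediate early gene (121 ± 74.4 and 1432 ± 509 CPM), JUNB (106 ± 34.3 and 428 ± 42.2 CPM), the small GTPase gene RHOB, the G-protein regulator GPSM1 (29.6 ± 7.39 and 221 ± 87.3 CPM), JOS1, SCUB2, MXRA8, SCMC2, LRIG1, a negative regulator of growth factor receptors, and PENK, which encodes proenkephalin (40.4 ± 8.01 and 168 ± 17.2 CPM). Their log2 fold changes lay between 2.10 for JUNB and 3.71 for BTG2. Those higher in rhino 1 included the matrix gene FBLN1 (584 ± 128 and 60.3 ± 4.45 CPM, log2 fold change -3.19), the smooth muscle gene SMTN (-3.09), the small heat shock protein gene HSPB1 (-2.75) and the cytokinesis gene RGAP1 (199 ± 12.7 and 23.1 ± 3.99 CPM, -3.02). KIF23, BUB1B, KIF22, KIF20A, KIF11, PLK1 and MCM5, genes of mitosis and DNA replication, completed the 12. The count was 626 by DESeq2 and 762 by limma-voom. It was 49 without rhino 1 replicate 1, the library on the other strand, with 30 of the 47 loci still called, 132 among the 7712 loci modelled on both strands, 4 without rhino 1 replicate 2, 1 without each of the 3 libraries of rhino 2, and 0 by edgeR without rhino 1 replicate 3, where 969 loci had an unadjusted p under 0.05.

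**Figure D2:**
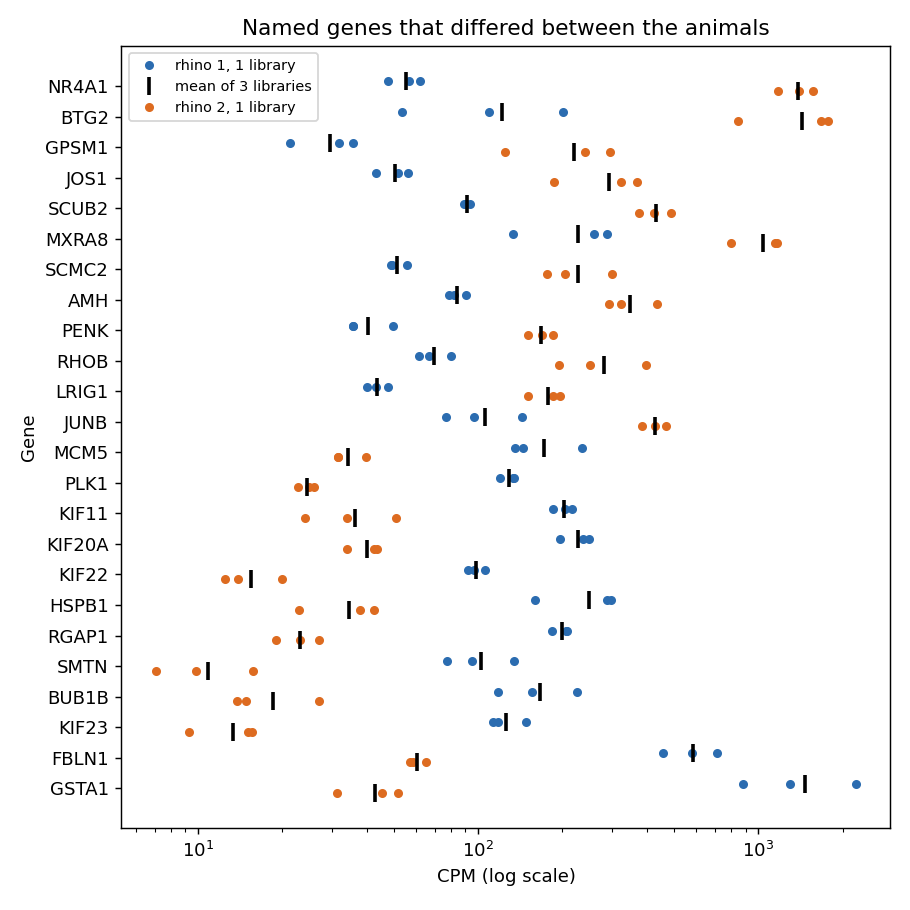
CPM on a log scale (horizontal axis) of the 24 named genes with the largest differences past the threshold, 12 in each direction. Each point is 1 library and each bar the mean of 3 libraries. The genes run from NR4A1 (55.4 against 1381 CPM) to GSTA1 (1469 against 42.8 CPM), and none overlaps between the animals because the rule that chose them required it.

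Cell cycle genes fell together in rhino 2 relative to rhino 1. Of 32 members tested, 31 had a negative log2 fold change, with a median of -2.22, and 9 passed the threshold over all genes, all lower in rhino 2, and 30 when adjusted over the list alone. The mitotic kinesin genes KIF23 (126 ± 18.9 and 13.3 ± 3.53 CPM, log2 fold change -3.15), KIF20A, listed as KI20A (227 ± 27.8 and 40.1 ± 5.21 CPM, -2.40) and KIF11 (202 ± 16 and 36.4 ± 13.6 CPM, -2.36), the spindle checkpoint kinase gene BUB1B (166 ± 54.7 and 18.5 ± 7.35 CPM, -3.12), the mitotic kinase gene PLK1 (129 ± 7.81 and 24.5 ± 1.65 CPM, -2.29) and the replication helicase gene MCM5 (171 ± 54.3 and 34.3 ± 4.78 CPM, -2.25) were among the 9. KIF22, outside the list, had a log2 fold change of -2.59. MKI67, listed as KI67, had 723 ± 228 and 131 ± 45.3 CPM and missed the threshold (log2 fold change -2.38, adjusted p = 0.0501). BUB1B and PLK1 are names on more than 1 locus. The list was lower in rhino 2 by camera (adjusted p = 7.3e-32) and by fry (adjusted p = 9.6e-04), with adjusted p = 0.031 with an estimated correlation. With any 1 of the 6 libraries left out, camera's call held, but no list passed with an estimated correlation, the smallest adjusted p of any list then lying between 0.091 and 0.208.

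Glycolysis genes were also lower in rhino 2, with 18 of 19 tested members negative and a median log2 fold change of -0.96. LDHA, which makes lactate from pyruvate, had 440 ± 87.6 and 111 ± 13.1 CPM (log2 fold change -1.89, adjusted p = 0.031) and was the only member past the threshold over all genes, against 11 adjusted over the list alone, and its name stands on 2 loci. PGK1 had 592 ± 140 and 186 ± 41.5 CPM (-1.58, adjusted p = 0.065), and the transporter genes SLC2A3 (-1.51) and SLC16A3 (-1.40) had adjusted p of 0.710 and 0.703. SLC2A3 turned to 0.45 without rhino 1 replicate 2. It had 178 CPM in that library, against 7.11 to 35.4 CPM in the others. SLC16A3 was -0.42 without rhino 1 replicate 1. Camera gave adjusted p = 1.2e-10, fry gave 7.2e-04, and the value was adjusted p = 0.031 with an estimated correlation. Oxidative phosphorylation genes had 33 of 36 members negative (median -0.42, camera adjusted p = 1.1e-07, adjusted p = 0.394 with an estimated correlation), with 0 past the threshold by edgeR over all genes, 3 adjusted over the list alone, 8 at an unadjusted p under 0.05, 4 by DESeq2 and 2 by limma-voom. Its largest differences were those of ATP5MC1 (-1.70), NDUFB5 (-1.39), ATP5MC3 (-0.98) and UQCRQ (-0.91), none past the threshold. Cholesterol synthesis and uptake genes had 19 of 25 members negative (median -0.62, camera adjusted p = 1.2e-04, adjusted p = 0.381 with an estimated correlation), with 0 past the threshold by edgeR over all genes, 4 adjusted over the list alone, 8 at an unadjusted p under 0.05, 6 by DESeq2 and 3 by limma-voom. TM7SF2 (-1.97), ACAT2 (-1.90), DHCR7 (-1.56) and FDPS (-1.48) had the largest. Antioxidant genes had 22 of 26 members negative (median -0.51, camera adjusted p = 2.0e-04, adjusted p = 0.381 with an estimated correlation), with GSTA1 the 1 member past the threshold over all genes and adjusted over the list alone. CAT (-2.37), TXNRD2 (-1.98) and NQO1 (-1.18) did not pass it.

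Immediate early genes rose in rhino 2 as a group, with all 21 tested members above 0 and a median log2 fold change of 1.56. NR4A1, BTG2 and JUNB passed the threshold over all genes, and 15 members did when adjusted over the list alone. NR4A2 had 13.2, 0 and 0 CPM in rhino 1 and 398, 121 and 244 CPM in rhino 2 (log2 fold change 5.36, adjusted p = 0.102). NR4A2 passed the threshold without rhino 1 replicate 1 (adjusted p = 0.043). In that fit the remaining libraries of rhino 1 were both at 0, so its log2 fold change of 11.2 is no bound. Camera gave adjusted p = 9.6e-13 and fry 0.0082, and the call was lost with adjusted p = 0.103 with an estimated correlation. Fry's call ended without rhino 1 replicate 2 (adjusted p = 0.0585) and without rhino 2 replicate 1 (0.0540) or 3 (0.121). Of markers of other cell types, MYH11 (2.01, adjusted p = 0.074) and TEK (1.47, adjusted p = 0.089) were also higher in each library of rhino 2 than in any of rhino 1. By edgeR these 2 did not pass the threshold. Inflammatory cytokine and chemokine genes had 5 of 6 members above 0 (median 0.77, camera adjusted p = 0.044, fry 0.036, adjusted p = 0.381 with an estimated correlation), with 0 past the threshold by edgeR over all genes, and 2 adjusted over the list alone, at an unadjusted p under 0.05, by DESeq2 and by limma-voom. CXCL10, an interferon-induced chemokine gene, had 3.31, 0 and 23.5 CPM in rhino 1 and 113, 68.2 and 126 CPM in rhino 2 (log2 fold change 3.58, adjusted p = 0.200), and PTGS2, the prostaglandin synthase gene of the ovulatory response, had 68.8 ± 4.97 and 145 ± 16.3 CPM (1.18, adjusted p = 0.062). CXCL8 (-0.97, but 0.35 without rhino 1 replicate 1) and NFKB1 (0.80) were further members. Camera's call on this list ended without rhino 1 replicate 3 (adjusted p = 0.138) and without rhino 2 replicate 1 (0.0501) or 3 (0.091), in a range from 0.0080 to 0.138. Fry's ended without any 1 of the 6 libraries (adjusted p from 0.073 to 0.228). Cytosolic ribosomal protein genes had 67 of 69 members above 0 (median 0.52, camera adjusted p = 4.5e-14, fry 0.133, adjusted p = 0.539 with an estimated correlation), with 0 past the threshold by edgeR over all genes or adjusted over the list alone, 29 at an unadjusted p under 0.05, 22 by DESeq2 and 12 by limma-voom. RPL9 (0.92), RPS27 (0.85), RPL5 (0.81) and RPS14 (0.81) had the largest, and RPL9, RPS27 and RPL5 are names on more than 1 locus. Heat shock genes went both ways. The median was -0.04, HSPB1 was lower in rhino 2, and DNAJB1 had 157 ± 16.1 and 488 ± 276 CPM (1.75, adjusted p = 0.109). HSPE1 (-1.22) and FKBP4 (-1.08) did not pass the threshold by edgeR. Of 15 members tested, 1 passed by edgeR over all genes, 5 by DESeq2 and 5 by limma-voom. Camera gave adjusted p = 0.044 towards rhino 1, with adjusted p = 0.447 with an estimated correlation, and 5 members were lower and 1 higher when adjusted over the list alone. That call ended without any 1 library other than rhino 1 replicate 3, with adjusted p between 0.025 and 0.106.

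Of the granulosa panel, CYP19A1, LHCGR, INHBA, INHBB and CCND2 lay higher in each library of rhino 1 than in any of rhino 2. NR5A1, CYP11A1 and MKI67 did so too, while AMH and PTGS2 lay higher in each library of rhino 2. Of all tested loci, 24.4% had no overlap between the animals. None of the panel genes higher in each library of rhino 1 passed the threshold in the main edgeR test of all 6 libraries. Of 16 alternatives, including other tools, CYP19A1 was called under 6, LHCGR under 2, INHBA and INHBB under 3 each and CCND2 under 0. CYP19A1, the aromatase gene of oestradiol synthesis, listed as CP19A, had 3418, 892 and 2929 CPM in rhino 1 and 180, 237 and 260 CPM in rhino 2 (log2 fold change -3.34, SE 0.54, adjusted p = 0.054). It passed without rhino 1 replicate 2 (adjusted p = 0.027). The LH receptor gene LHCGR, listed as LSHR, had 132 ± 66.4 and 27.2 ± 9.37 CPM (-2.21, adjusted p = 0.123). INHBA and INHBB, the genes of the activin and inhibin beta subunits, had log2 fold changes of -1.56 (579 ± 215 and 186 ± 24.7 CPM, adjusted p = 0.095) and -1.64 (3386 ± 1432 and 1016 ± 438 CPM, adjusted p = 0.156). CCND2, a cyclin gene of dividing granulosa cells, had 530 ± 159 and 250 ± 70.2 CPM (adjusted p = 0.251). The steroidogenesis list had 10 of 16 members negative (median -0.36, camera adjusted p = 0.103), with 0 past the threshold over all genes by edgeR, 2 at an unadjusted p under 0.05, and 1 adjusted over the list alone, by DESeq2 and by limma-voom. STAR (2.40), CYP11A1 (-2.22) and SCARB1 (-0.84) did not pass it.

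**Figure D3:**
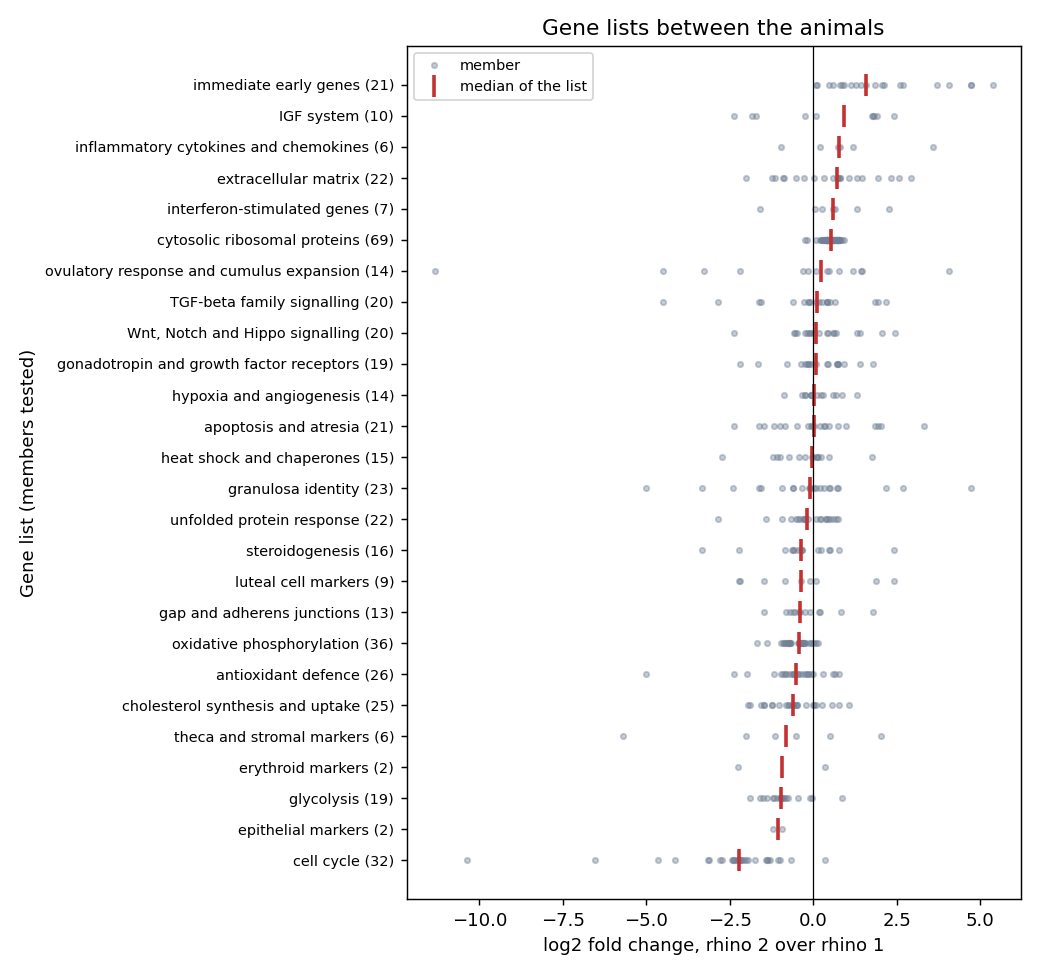
Log2 fold change of rhino 2 over rhino 1 (horizontal axis) for each tested member (points) of the 26 lists tested, with the median of each list (bars). Cell cycle genes have the lowest median (-2.22) and immediate early genes the highest (1.56).

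No other process list passed camera. The granulosa identity list (23 tested, median -0.10, adjusted p = 0.719) held NR4A1 and AMH higher and GSTA1 lower in rhino 2. When adjusted over the list alone, 4 were higher and 5 lower, and fry placed this list towards rhino 2 (adjusted p = 0.541) although its median was negative. The ovulatory list had a median of 0.24 and camera direction towards rhino 2 (adjusted p = 0.932) but a mean of -0.85, with CD44 at 296 CPM in rhino 1 replicate 2 and 18.4 and 28.3 CPM in replicates 1 and 3, GREM1 at -4.49 and PTX3 at -3.28, none past the threshold. In rhino 1, replicates 1, 2 and 3 had 0.376, 294 and 53.1 CPM of GREM1, which turned to 2.18 by limma-voom. They had 22.0, 772 and 164 CPM of PTX3, which was -1.58 without replicate 2. RGS2 (4.07, adjusted p = 0.082) went the other way, and 2 members were higher and 2 lower adjusted over the list alone. CD44 had no counts in rhino 2, so its fitted value, which the mean of the list includes, is no bound. The TGF-beta family list had a median of 0.12 and a mean of -0.15 (camera towards rhino 2, adjusted p = 0.719). By edgeR, AMH passed the threshold, while GREM1, FSTL3 (-2.86, but 1.79 by limma-voom and -0.67 without rhino 1 replicate 2) and SKIL (1.94) did not. DESeq2 and limma-voom each called 4 members of that list, against 1 by edgeR, and 2 were higher and 2 lower adjusted over the list alone. Among receptors (median 0.07, adjusted p = 0.485; 2 higher and 1 lower adjusted over the list alone), IGF1R had 92.1 ± 26.4 and 302 ± 61.5 CPM (1.79, adjusted p = 0.054, and 0.036 without rhino 1 replicate 1), BMPR2 1.39 and BMPR1A -1.67. The IGF list had a median of 0.91 (adjusted p = 0.191, 2 higher adjusted over the list alone), with IGFBP7, listed as IBP7, at 200 ± 59.9 and 698 ± 231 CPM (1.90, adjusted p = 0.068), STC1 at 2.41, IGFBP4 at -1.84 and IGFBP5 at -2.39. Without rhino 1 replicate 1 the IGF list passed camera (adjusted p = 0.023, in a range from 0.023 to 0.259 over the alternatives), a call lost with adjusted p = 0.567 with an estimated correlation. Extracellular matrix genes (median 0.72, adjusted p = 0.116, 5 higher adjusted over the list alone) included MMP14 (2.92), NID2 (2.57), LAMA5 (2.32) and COL4A6 (-2.02), none past the threshold by edgeR. That list passed camera without rhino 1 replicate 2 (adjusted p = 0.0049, in a range up to 0.901), a call lost with adjusted p = 0.509 with an estimated correlation. Its median turned to -0.23 without rhino 2 replicate 1. The ovulatory, receptor, IGF and extracellular matrix lists had 0 members past the threshold by edgeR over all genes. Their members at an unadjusted p under 0.05 numbered 5, 5, 3 and 9, with 5, 3, 2 and 6 called by DESeq2 and 3, 2, 5 and 4 by limma-voom.

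Apoptosis genes had a median of 0.00 and a mean of 0.13 while camera pointed towards rhino 1 (adjusted p = 0.719, 1 higher adjusted over the list alone). CLU, listed as CLUS, had 1183 and 1281 CPM in rhino 2 replicates 1 and 3 and 86.7 CPM in replicate 2, against 53.1 to 119 CPM in rhino 1 (3.32, adjusted p = 0.172), and GADD45A (2.01) and BCL2L11 (1.95) did not pass the threshold. Hypoxia genes (median 0.02, mean 0.15, camera towards rhino 1, adjusted p = 0.965) included THBS1 (1.31), SLC2A1 (-0.87), EPAS1 (0.86) and BNIP3L (0.69). The unfolded protein response list (median -0.21, adjusted p = 0.323) included SDF2L1 (-2.85), ASNS (-1.41), CALR (-0.95) and PPP1R15A (0.74). The junction list (median -0.39, adjusted p = 0.218) included OCLN (1.77), PKP2 (-1.49, but 0.19 with strands joined at any overlap) and DSG2 (-0.81), and it passed camera without rhino 1 replicate 3 (adjusted p = 0.024, in a range up to 0.570), a call lost with adjusted p = 0.569 with an estimated correlation. The interferon list (median 0.58, adjusted p = 0.350) included IRF1 (2.25, but 3.72 without rhino 1 replicate 1), USP18 (-1.59), DDX58 (1.32) and RSAD2 (0.66). In the hypoxia, unfolded protein, junction and interferon lists, 0 members passed the threshold by edgeR over all genes or adjusted over the list alone. Their members at an unadjusted p under 0.05 numbered 1, 4, 2 and 1, with 1, 2, 1 and 0 called by DESeq2 and 1, 2, 0 and 0 by limma-voom. The Wnt, Notch and Hippo list (median 0.09, adjusted p = 0.226, 2 higher adjusted over the list alone) included the Notch target gene HES1 (18 ± 1.85 and 92.4 ± 38.4 CPM, 2.45, adjusted p = 0.058), the Wnt antagonist gene SFRP4 (174 ± 34.0 and 668 ± 239 CPM, 2.05, adjusted p = 0.0501), APC (-2.39) and LRP5 (1.41). The apoptosis list and this list had 0 members past the threshold by edgeR over all genes, with 4 and 3 at an unadjusted p under 0.05, 2 and 3 called by DESeq2 and 2 and 3 by limma-voom. Medians of other lists also took both signs over the alternatives, from -0.29 to 0.23 for granulosa identity, -0.31 to 0.60 for the ovulatory list, -0.01 to 0.45 for receptors and -0.0048 to 0.28 for the TGF-beta family. The ranges were -0.25 to 0.04 for heat shock, -0.27 to 0.33 for apoptosis, -0.09 to 0.14 for hypoxia, -0.29 to 0.02 for the unfolded protein response and -1.97 to 0.05 for theca and stromal markers. Without a change of sign, medians moved by over 1.5 times in the IGF (0.79 to 1.48), interferon (0.20 to 0.75), Wnt, Notch and Hippo (0.03 to 0.40), epithelial (-1.62 to -0.58) and luteal lists (-0.94 to -0.40). Fry called the IGF list without rhino 2 replicate 2 (adjusted p = 0.0457) and the epithelial list without rhino 1 replicate 3 (adjusted p = 0.0257).

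Markers of other cell types differed between libraries. HBB/HBE2, a locus of beta-like globin genes, had 4335, 1963 and 2987 CPM in rhino 1 and 387, 809 and 631 CPM in rhino 2 (log2 fold change -2.26, adjusted p = 0.072). It thus moved with the lists that were lower in rhino 2, cell cycle and glycolysis among them. CA1, listed as CAH1, lay between 26.9 and 44.2 CPM. The erythroid list as a whole had an adjusted p of 0.263, with 1 of 2 members lower adjusted over the list alone. Among theca and stromal markers, ACTA2, listed as ACTA, had 39.6, 2292 and 393 CPM in rhino 1 and 9.84, 41.2 and 0 CPM in rhino 2, and the collagen gene COL1A1, listed as CO1A1, had 4.67, 2870 and 353 CPM in rhino 1 and no counts in rhino 2. COL1A2, listed as CO1A2, had 2909 CPM in rhino 1 replicate 2 and 460 to 1178 CPM in the other libraries, COL3A1 had 619 CPM there and 93.7 to 196 CPM elsewhere, and RGS5 had a log2 fold change of -2.03. Summed markers of this list reached 9122 CPM in rhino 1 replicate 2, against 999.9 CPM in replicate 1 and 2141.5 CPM in replicate 3 and 2207, 1214 and 2024 CPM in rhino 2. MYH11 of the same list went the other way, at 188 ± 73.3 and 721 ± 187 CPM (2.01, adjusted p = 0.074). The list did not pass camera (median -0.83, adjusted p = 0.448, 1 higher and 1 lower adjusted over the list alone), but did without rhino 1 replicate 1 (adjusted p = 0.0014, in a range from 0.0014 to 0.838), a call lost with adjusted p = 0.446 with an estimated correlation. TEK, an angiopoietin receptor gene of endothelial cells, listed as TIE2, had 78.6 ± 21.2 and 206 ± 47.2 CPM (1.47, adjusted p = 0.089), while VWF had at most 3.94 CPM and EMCN, at a locus with no opposite-strand model, had 6.85 CPM in rhino 1 replicate 1. Of 24 leukocyte markers matched, 20 had counts in rhino 1 replicate 1 and 0 had counts in all 6 libraries. They were led there by CD74, listed as HG2A, at 70.1 CPM and PTPRC at 26.6 CPM. That library was the deepest and the one with its counts on named genes. Of 2990 named loci with counts there but no opposite-strand model, 2757 were at 0 in the other 5, where such zeros say nothing. CD68 had at most 26.9 CPM. Of 20 oocyte markers, GDF9 (3.91 CPM) and NLRP5 (0.527 CPM) had counts, both in rhino 1 replicate 1 alone and at loci with no opposite-strand model. The epithelial list (median -1.07, adjusted p = 0.327) rested on KRT8 (285 ± 207 and 113 ± 47.9 CPM) and KRT18 (-0.95, but 0.43 without rhino 1 replicate 2), and passed camera without rhino 1 replicate 3 (adjusted p = 0.0030, in a range up to 0.941), a call lost with adjusted p = 0.569 with an estimated correlation. KRT19 had 93.4, 223 and 6.21 CPM in rhino 1 and no counts in rhino 2. Luteal markers (median -0.38, adjusted p = 0.218, 1 higher and 2 lower adjusted over the list alone) included AKR1B1 (1.86) and HSD3B1 (-0.38), none past the threshold. By edgeR over all genes, 0 members of the theca and stromal, erythroid, epithelial and luteal lists passed, with 3, 1, 0 and 3 at an unadjusted p under 0.05, 1, 1, 0 and 3 called by DESeq2 and 1, 1, 0 and 0 by limma-voom. Of mitochondrially encoded genes, only NU4LM was tested among the list's members, at 5339 CPM in rhino 1 replicate 1 and between 17.7 and 53.8 CPM in the others, at a locus with no opposite-strand model.

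Libraries of rhino 2 resembled each other more than those of rhino 1 did. Across loci, Spearman correlations lay between 0.865 and 0.925 within rhino 2 (Pearson 0.746 to 0.856), between 0.663 and 0.806 within rhino 1 (Pearson 0.498 to 0.711) and between 0.693 and 0.826 between the animals (Pearson 0.523 to 0.764), over 15 pairs in all. On the genes as deposited, with strands not joined, rhino 1 replicate 1 had correlations of 0.191 to 0.209 with the other 5 libraries. No pair within an animal agreed within sampling noise, the chi-square per degree of freedom being between 7.75 and 128. The first principal component, 43.8% of the variance, set rhino 1 replicate 2 apart from the other 5 libraries.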

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

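The joining of strands, and the alternatives of the genes as deposited, of strands joined at any overlap and of loci modelled on both strands, were chosen after seeing the data, and the other alternatives were set before. The number of loci that differed between the animals, 47, was 353 with no filter on low counts, 626 with DESeq2, 762 with limma-voom (618 higher in rhino 2 and 144 higher in rhino 1), 84 with strands joined at any overlap and 132 on loci modelled on both strands. By edgeR it was 0 on the genes as deposited, with 239 at an unadjusted p under 0.05, and the cause there is the construction, since 1 library then has its counts on other genes, and 39 were called there without that library. With each library left out in turn it ranged from 0 to 49. DESeq2 size factors gave 63 and the removal of mitochondrial DNA genes 53, and all 47 loci were called under both, as they were by DESeq2, with no filter and at any overlap, against 45 by limma-voom. Of the 47, 44 were modelled on both strands, and all 44 were called there. The minimum of 5 CPM removed no locus and the minimum log2 fold change of 1 no call, so neither says anything about stability. No call changed sign, except that 1 of the 2 loci tested on the genes as deposited had the opposite sign, uncalled. The fits without a library hold fewer samples, and for the other changes the cause was not tested.

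The replicate number as a block gave 0 loci by edgeR, with 893 at an unadjusted p under 0.05. Same-numbered libraries of the animals had correlations of their deviations of 0.193, 0.124 and 0.0059, and differently numbered ones lay between -0.167 and 0.0152. Each library of rhino 2 except replicate 3 correlated best with its own number. The main test, set before the data were examined, did not pair the libraries. These values leave pairing open, and the calls of the main test rest on its absence. With the block, 7 lists passed camera and 0 passed fry, the smallest fry adjusted p being 0.066, and 0 passed camera with an estimated correlation, the smallest adjusted p being 0.433. The inflammatory and heat shock lists lost camera's call with the block (adjusted p = 0.0592 for each).

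The number of lists past camera, 9, was 2 with an estimated correlation, 9 with DESeq2 size factors and 7 to 10 with each library left out. Cell cycle, glycolysis, immediate early, oxidative phosphorylation, ribosomal protein, cholesterol and antioxidant genes passed camera with the same direction under all 8 other fits, but with an estimated correlation the first 2 passed under 1 of the 8 and the other 5 under 0, the smallest adjusted p of those 5 being 0.114. The cell cycle median ranged from -2.31 to -2.08 and the immediate early median from 1.31 to 1.83. Loci detected in both animals, 5758, became 8643 in at least 2 and 10430 in at least 1 of 3 libraries and 666 on the genes as deposited, and ranged from 5775 to 6853 with a library left out. For rhino 1 these counts were 9649, 14303 and 714. The share of the top 10 loci ranged from 9.94% to 10.7% with a library left out. The lowest correlation between libraries, 0.663, was 0.191 on the genes as deposited. The files hold counts alone, so a pseudocount on normalized values or FPKM in place of TPM did not apply, and no locus was named as ribosomal RNA. Depth limits detection, since 1 count is worth 1.49 CPM in the smallest library. In the simulated data at these depths 24% of 4-fold changes were called. No other depth was simulated, so that share cannot be divided between depth and the spread between libraries. With all libraries thinned to the smallest total, a check chosen after the results were seen, 90 loci passed by edgeR, against 47 at the full totals.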

Other observations

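All tests in this part were chosen after the results they bear on were seen. Counts of 0 at loci with counts elsewhere were most frequent in rhino 1 replicate 2 of the 6 libraries. Of 3901 loci modelled on both strands for which the other libraries predicted at least 20 counts there, 202 (5.18%) were listed at 0 and 1 lay above 0 but under 10% of its prediction. In rhino 2 replicate 2, the next smallest library, 48 of 3819 such loci were at 0, and in the other 4 libraries 3 to 9 were.

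Genes on scaffold Y_244 took 2.52% of the counts in rhino 1 replicate 2 (95% Wilson interval 2.49 to 2.56), 3.83% in rhino 2 replicate 2 (3.79 to 3.88) and 2.47% in rhino 2 replicate 3 (2.44 to 2.50). They took 0.756% in rhino 1 replicate 3, 1.14% in rhino 2 replicate 1 and 0.0037% (0.0034 to 0.0040) in rhino 1 replicate 1. Genes on the mitochondrial scaffold took 0.564% (0.560 to 0.568) in that library, 2.85% (2.81 to 2.89) in rhino 1 replicate 2 and 1.57% to 1.68% in the other 4. Rhino 1 replicate 1 is the library on the other strand, and these shares depend on which strand was modelled. They therefore cannot be compared with those of the other libraries as amounts of RNA.

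The first pattern weighed is the strand of the counts. RNA made from the opposite strand would have its own splice sites, but 93.6% of introns in the opposite-strand models were identical to those of the named gene, which argues against it. Reads without strand information would split evenly if strand were set by the reads alone, but at most 0.249% of loci in any library had 40 to 60% of their counts on each strand. In every library at least 97.6% of loci had over 90% of their counts on 1 strand. Libraries that keep strand, counted with opposite settings in rhino 1 replicate 1 and in the other 5, could give this. Strand can also be assigned from splice sites or gene models. Reads without strand information are therefore not excluded for rhino 1 replicate 1, whose counts lay on named genes. For the other 5 libraries, with counts opposite the named genes, the lack of an even split argues against them. Whether the directional kit was used, and which libraries follow the named strand by intent, stays open.

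The second pattern is the cell cycle list. Its median was -2.22 after all libraries were thinned to the smallest total. Random thinning keeps each locus's expected share of the counts, so this value decides nothing about a difference in depth. Without rhino 1 replicate 1, the deepest library, the totals of the animals overlapped (672410 and 1449450 against 703708 to 1523904 counts). The median was then -2.18, with 31 of 32 members negative, which argues against a difference in depth as the cause. Dividing cells of another type in the samples of rhino 1 were tested first by their highest marker, which was COL1A2 at 34.9% of INHA in rhino 1 replicate 2, with HBB/HBE2 at 34.0%, 23.5% and 24.1% in replicates 1, 2 and 3, and this left them open. A narrower test chosen after that outcome argues against theca or stromal cells as the whole cause, by the median of -2.28 without rhino 1 replicate 2, the library with the highest summed markers of those cells. Follicles at different stages of growth could also give this pattern, but the test made of it, the signs of CYP19A1, LHCGR, INHBA, INHBB, CCND2 and AMH, 6 of 6 as named, decides nothing, since these genes were taken from the panel after their directions were seen and CCND2 is also in the cell cycle list. With 1 animal in each group, stage, animal and collection cannot be told apart, and other cells stay open too. The globin locus moved with the list, but only 2 of 11 erythroid markers matched had counts, so it does not show dividing cells.

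The third pattern is the immediate early list. Its median was 1.5 after thinning, which for the same reason decides nothing about depth. Without rhino 1 replicate 1, where the totals of the animals overlapped, it was 1.83, with 20 of 21 members above 0. That argues against a difference in depth as the cause. Stress during collection could raise such genes, but the heat shock list had a median of -0.039 over 15 members that went both ways, which decides nothing. A difference between the animals or in the handling of their samples therefore stays open.

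The 6 libraries make only 10 splits into 3 and 3, too few for a share under 0.05. For loci past the threshold, 1 split, the real one, gave as many, with 47 loci against a highest of 0 in the others. For lists past camera, 2 splits gave as many, with 9 lists in the real split and a highest of 9 in the others. The splits that mixed the animals passed camera with 2 to 9 lists, so the number of camera's calls does not set the real split apart. By fry the real split gave 4 lists, against a highest of 1 in the others.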
